A study of Mus musculus with 6 samples.

How the data were processed

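The series measured messenger RNA in neonatal mouse ventricular cardiomyocytes, with 6 samples in the labels, 2 per group, treated with DMSO, cyclopamine or GANT61. A Smoothened agonist named in the treatment protocol is not analysed here. Per the labels' protocols, cells were plated at 70000 per well in 12-well plates and libraries were made with a stranded mRNA kit. Per the submitters' processing notes, Trimmomatic 0.33, FastQC, HISAT2 2.1.0, featureCounts and the GRCm38 build were used, with no role or order given. The annotation and the strand setting of the counting are not given in the sources used here. Antisense and overlapping genes can therefore share reads, and genes with near-identical copies can lose or gain reads.

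The values used are raw read counts per gene as the authors deposited them, whole numbers per the file headers and values, with no normalization. The table has 55487 genes, of which 22450 had a count in any library, and 3 columns of counts, 1 per group. The column names give the group and a code that the labels tie to no replicate, and do not say whether replicates were pooled. The authors also deposited lists of higher and lower genes, whose rows hold the same counts. Gene IDs were matched to the GENCODE mouse release 21 annotation of GRCm38 for 55227 of the genes, and positions are given from it. As a check of shared sequence, the share of 50-base windows of the longest transcript of each list gene that occur in another annotated gene was computed, which also catches overlapping gene models.

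The design fixed before the data were examined was an edgeR fit of 6 samples with 3 groups. With 1 column per group that model has no residual degrees of freedom, so pairwise comparisons were made without a test. The size rule (at least 1.5-fold, with an exact conditional binomial 95% counting interval that excludes no difference, and for the mean of both inhibitors the same direction in each) and the test of both inhibitor libraries against DMSO were chosen after the files had been seen. The same test was run with each inhibitor library as the lone library. Genes were kept by edgeR's filterByExpr (15576 genes), scaled by TMM, and expressed as log2 CPM with a prior count of 2. The 2-arm test used edgeR's quasi-likelihood fit with robust estimation and Benjamini-Hochberg adjustment. As a summary, the common dispersion was 0.0355 (coefficient of variation 0.188), and the simulations used the dispersion trend over genes. DESeq2's Wald test and limma-voom were alternatives. The spread between cyclopamine and GANT61 enters as error in this test, and its p-values measure only that spread.

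The 43 gene lists were fixed before the data were examined, and 42 had at least 5 members past the filter. Each list's median log2 fold change was placed among 10000 random lists of the same size drawn from the same of 20 bins of mean expression, as a description of these libraries. On the 2-arm contrast camera was run with a correlation preset at 0.01 and with an estimated correlation, and fry beside it. Named genes were fixed by rule as the 10 highest and 10 lowest by fold per comparison with a mean of at least 5 CPM. Symbols that are only Gm numbers, Rik clones or accessions were passed over in this ranking. The rule added up to 4 members per list, and Gli1, Gli2, Gli3, Ptch1, Hhip and Smo. The rule asked for genes called by the test and was applied to genes past the size rule. Of each list the members with the largest fold were named, and other members, such as Foxm1, Bcl2, Cdc25c, Ccng1, Thy1, Lyz2 and the deep mitochondrial genes, were chosen after their values were seen. Some genes that the rule selects are not reported here. A gene with 0 counts was compared at a floor of 3 counts per library. Shared controls were simulated with 100 data sets of unchanged libraries, with Poisson noise or with the fitted dispersions.

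The size rule, the list percentiles and the 2-arm tests of edgeR and DESeq2 were tested on simulated data with 200 genes and a further list of 25 genes altered in both inhibitor libraries among 15576. limma-voom, camera and fry were not tested in this way. For cyclopamine against DMSO with counting noise alone, the size rule found 87 of 100 genes altered 2-fold and 98 of 100 altered 4-fold, and 109 of 15351 unaltered genes. With the spread between the inhibitors it found 74 and 96, and 2272 unaltered genes. In the 2-arm test with that spread, edgeR called 44 of 125 genes altered 2-fold, 73 of 100 altered 4-fold and 5 of 15351 unaltered genes. Both inhibitor libraries had the same fold in this simulation, and each gene took its dispersion from the trend, without scatter between genes. These rates may therefore be higher than those for the real libraries. The list of 25 genes, altered 2-fold, reached percentile 100 in cyclopamine against DMSO. Alternatives tried were DESeq2 size factors, library size only, no filter, a filter of at least 5 CPM in 2 libraries, other tests and thresholds, 1.2-fold and 2-fold, and no counting interval. Analyses used R 4.3.3, edgeR 4.0.16, DESeq2 1.42.0, limma 3.58.1, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.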

Results

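Messenger RNA was sequenced from cultured ventricular cardiomyocytes of neonatal mice, isolated at postnatal day 1 or 2 and depleted of fibroblasts with CD90 antibodies. After 12 h in culture the cells were treated for 48 h with DMSO, the solvent control, with cyclopamine at 5 µg/ml or with GANT61 at 3 µM. Cyclopamine is a plant alkaloid that blocks Smoothened, the membrane protein that relays the Hedgehog signal, and GANT61 blocks the GLI transcription factors at the end of that pathway. The doses are given in different units, so the compounds are set side by side and not matched for dose. The labels list 6 samples, 2 per group, but the count table holds 1 column per group, and whether a column is a single replicate or a pool is not stated. No difference between groups below therefore has a replicate check. The columns held 36661845 counts for DMSO, 38966515 for cyclopamine and 35461530 for GANT61, and 20120, 19774 and 19425 genes had at least 1 count. Mitochondrial genes took 5.21% of the counts in DMSO, 6.42% in cyclopamine and 5.02% in GANT61, and mitochondrial ribosomal RNA took 0.133%, 0.282% and 0.236%. Genes were compared by their log2 fold change over the 15576 genes past an expression filter. A gene is called higher or lower by size when it differed by at least 1.5-fold and its exact 95% counting interval excluded no difference. Counting intervals cover counting error only, not the variation between cultures. For a list of genes fixed in advance, the percentile is the share of 10000 random lists of like expression whose median log2 fold change was smaller.

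Genes of the Hedgehog pathway were read first, because both compounds act on it. Gli1 (chromosome 10, 127329882 to 127341974, GRCm38), a direct GLI target and itself a GLI factor, had 7 counts in DMSO (exact Poisson interval 2.81 to 14.4) and 0 in each inhibitor library. With a floor of 3 counts per library, and with the DMSO count taken as exact, Gli1 was at least 2.43-fold lower in cyclopamine and at least 2.27-fold lower in GANT61. With counting error in both libraries the upper bounds of its log2 ratio to DMSO were -0.59 and -0.49. The ligand gene Shh had 8 counts in DMSO and 0 in each inhibitor library, and the target Hhip had 0 counts in all 3, so Hhip could not be compared at this depth. Ptch1 (chromosome 13, 63508328 to 63573598), the Hedgehog receptor and the target with the deepest counts of these, had 1437 counts in DMSO, 1368 in cyclopamine and 1168 in GANT61, with log2 fold changes of -0.13 (counting interval -0.24 to -0.02) and -0.26 (-0.37 to -0.15). Smo (chromosome 6, 29735503 to 29761365), which encodes Smoothened, was lower at -0.31 (-0.46 to -0.16) in cyclopamine and -0.77 (-0.94 to -0.60) in GANT61. Gli2 had 16, 11 and 14 counts, and its interval included no difference in both comparisons. Gli3 had 205, 187 and 150 counts, with log2 fold changes of -0.19 (-0.49 to 0.10) and -0.41 (-0.72 to -0.10). Among 19 measured pathway components the median log2 fold change was -0.19 in cyclopamine (percentile 2.52) and -0.30 in GANT61 (percentile 2.93). For the mean of both inhibitors it was -0.29 (percentile 0.94), with 0 higher and 3 lower by size. In cyclopamine Gpr161, a negative regulator at the cilium, was the only component lower by size, whereas Smo, the co-receptor genes Cdon (-1.33) and Boc (-0.68) and Gpr161 (-0.83) were lower by size in GANT61. Among 15 measured Hedgehog and GLI target genes the medians were -0.03 (percentile 34.2) and -0.09 (percentile 24.1). By size 0 were higher and 2 lower in cyclopamine, and 2 higher and 3 lower in GANT61. Foxm1, a mitotic transcription factor on that list, was at -1.63 and -2.04, Snai1 at -1.11 and -0.68, and Bcl2 at 0.42 and 0.62. Among 26 genes of the primary cilium the medians were -0.07 (percentile 19.2) and -0.19 (percentile 4.09), with 0 and 2 members lower by size.

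**Figure D1:**
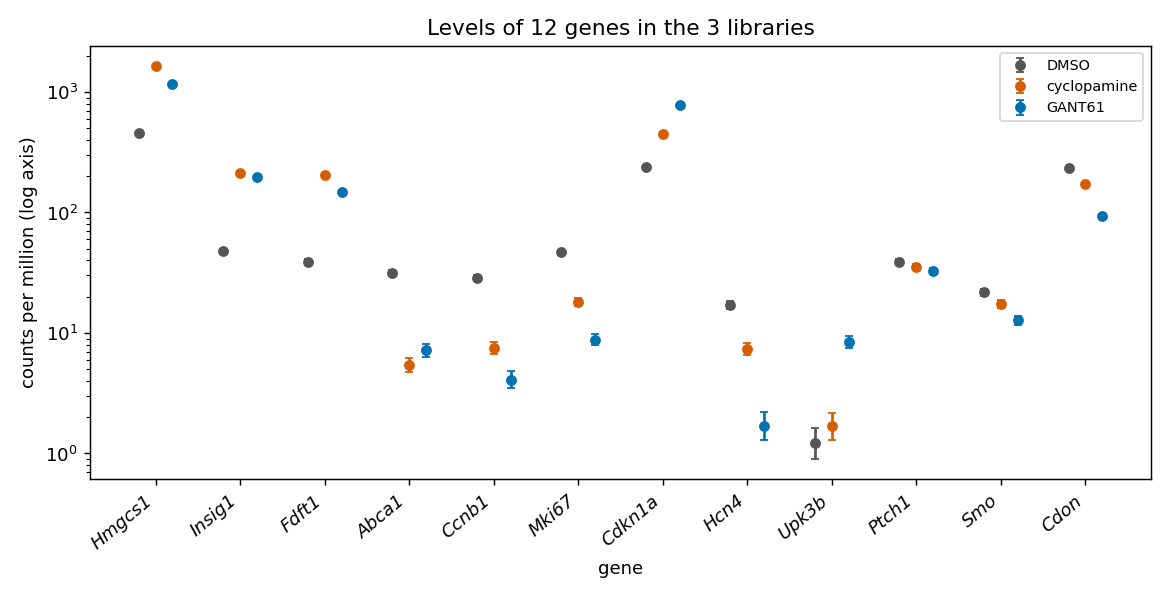
CPM on a log axis for 12 genes in the DMSO, cyclopamine and GANT61 libraries, 1 point per library with its exact 95% Poisson interval, which covers counting error only; the genes were chosen after their values were seen. Hmgcs1, Insig1 and Fdft1 stood higher in both inhibitor libraries, Abca1, Ccnb1 and Mki67 lower, Upk3b apart in GANT61, and Ptch1 close to its DMSO level.

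Cyclopamine against DMSO addressed inhibition at the level of Smoothened. Genes of cholesterol synthesis and uptake stood higher together: of 25 measured cholesterol synthesis genes and targets of SREBP2, the transcription factor of the sterol response, 23 were higher by size and 0 lower, with a median log2 fold change of 1.47 (percentile 100). Fdft1 (chromosome 14, 63145150 to 63179578), which encodes squalene synthase, had 1433 counts in DMSO and 7919 in cyclopamine, a log2 fold change of 2.40 (2.32 to 2.49). Insig1 was at 2.16 (2.09 to 2.24), Idi1 at 2.12 (2.02 to 2.22) and Msmo1 at 2.08 (2.01 to 2.14). Fdps, at 2.13, rests on 44 counts in DMSO and shares part of its sequence with other annotated genes, so its level is uncertain. Of 20 LXR targets and fatty acid synthesis genes, 8 were higher by size and 2 lower (median 0.37, percentile 100). The desaturase genes Scd1 (1.95) and Scd2 (1.34) and the fatty acid synthase gene Fasn (0.94) stood higher. The 2 lower members were sterol exporter genes and LXR targets, Abca1 (chromosome 4, 53030787 to 53159895) at -2.53 (-2.76 to -2.32) with 1163 counts against 209, and Abcg1 at -1.76 (-2.13 to -1.44). The metallothionein gene Mt2, which encodes a metal-binding protein, was at 3.24 (2.99 to 3.55), and its neighbour Mt1 had 503 counts in DMSO and 2251 in cyclopamine. Of 5 measured metallothionein and zinc response genes 3 were higher and 1 lower by size.

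Cell cycle genes stood lower in the cyclopamine library. Of 39 G2/M and mitosis genes, 38 were lower by size (median -1.52, percentile 0), among them Cdca8 (-2.01), Cenpf (-1.97), Ccnb1 (-1.91) and Ccnb2 (-1.90), and Dlgap5, another mitotic spindle gene, was at -2.19. Of 39 DNA replication and S phase genes, 27 were lower by size (median -0.84, percentile 0), with Clspn at -1.52 and Rrm2 at -1.51. Of 24 p53 target genes, 7 were higher by size and 1, Ckap2, lower (median 0.47, percentile 100). Gdf15 was at 1.16, Eda2r at 0.99 and Cdkn1a, which encodes the CDK inhibitor p21, at 0.91. Few contractile genes differed by size: of 32 sarcomere genes, Myom2, an M-band protein gene, was higher by size at 1.33 and Myl4, the atrial light chain gene, lower at -1.03 (median -0.04, percentile 4.05). Of 29 genes of mature cardiomyocytes, 3 were higher by size, Myom2, the myoglobin gene Mb (1.10) and Ppara (0.80), and 0 lower (median 0.21, percentile 100). Of 21 measured fetal or immature cardiomyocyte genes, 0 were higher by size and 5 lower (median -0.10, percentile 1.74), Hcn4 (-1.21), Acta1 (-1.16), Myl4, H19 (-0.81) and Acta2 (-0.73). Tnnt3, the fast skeletal troponin T gene, was at -2.26 (-2.64 to -1.96) and Wscd2 at -2.02 (-2.24 to -1.81). Macrophage and leukocyte markers had 4 of 11 higher by size and 0 lower. Fibroblast, endothelial and smooth muscle markers had medians slightly below 0, and some of them passed the size rule. The median was -0.26 over 20 fibroblast markers (percentile 0.04, 1 higher and 2 lower by size). It was -0.26 over 19 endothelial markers (percentile 0.93, 0 higher and 2 lower). Over 11 smooth muscle and pericyte markers, which went both ways, it was -0.25 (percentile 0.63, 2 higher and 3 lower). The last of these lists held Cnn1, which was at -1.81. Over 39 collagen and matrix genes the median was -0.21 (percentile 0), with 1 higher and 6 lower by size. In all, 638 genes were higher and 1133 lower by size. The total was 447 when genes had to reach 5 CPM in 2 libraries. Counting noise alone gave 129 such genes on average in 100 simulated data sets. Counts drawn with the spread seen between the inhibitor libraries gave 2300, more than the 1771 observed, so this count is not larger than that spread.

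**Figure D2:**
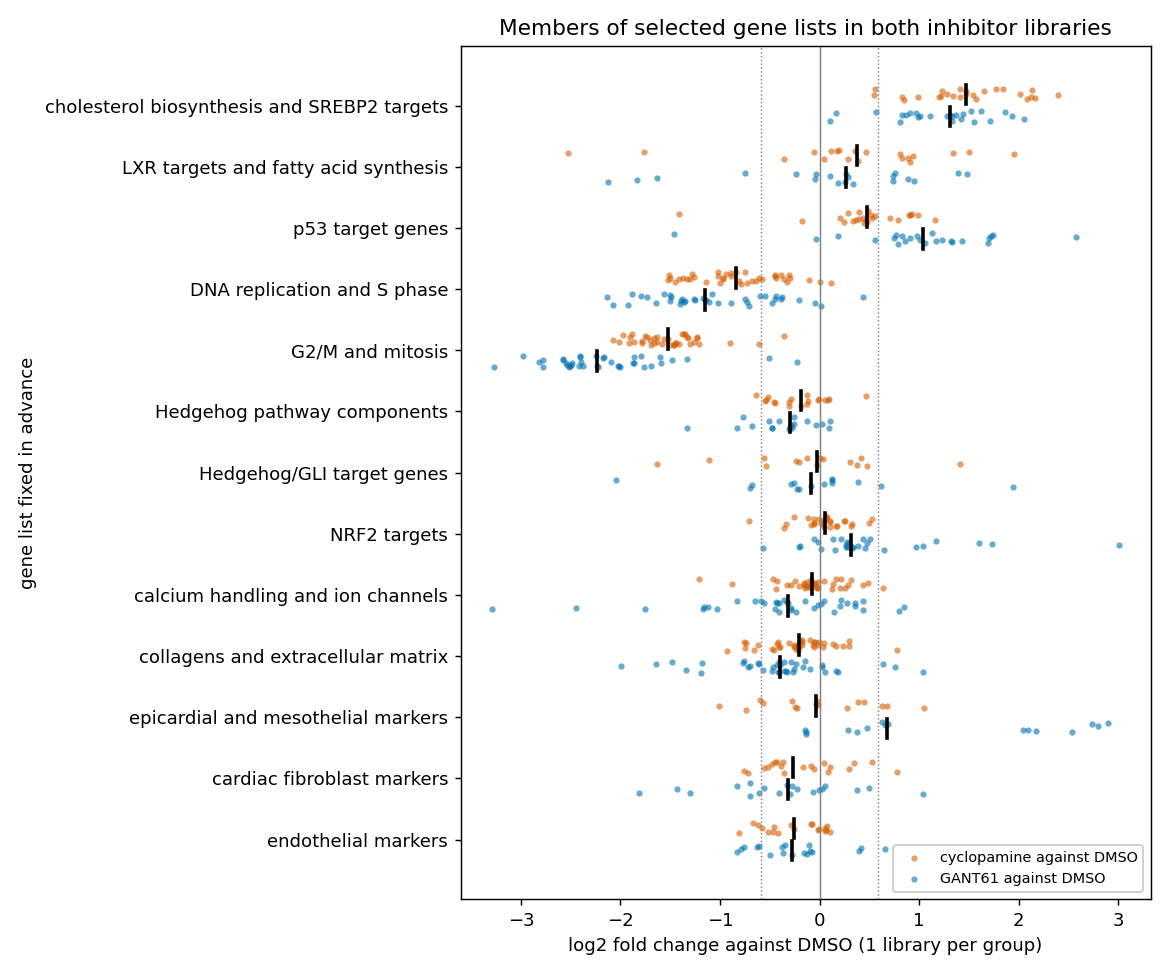
Log2 fold change against DMSO (x axis) of each measured member of 13 gene lists fixed in advance (y axis), in orange for cyclopamine and blue for GANT61, with a black bar at each list's median and dotted lines at 1.5-fold; each group is 1 library. The cholesterol list lies to the right in both comparisons (medians 1.47 and 1.31) and the G2/M list to the left (-1.52 and -2.24).

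GANT61 against DMSO addressed inhibition at the level of the GLI factors. Cholesterol genes again stood higher, 22 of 25 by size (median 1.31, percentile 100), with Insig1 at 2.05, Fdft1 at 1.93 and Msmo1 at 1.86. Of the LXR and fatty acid synthesis list 7 were higher and 4 lower by size (median 0.27, percentile 99.7), with Abca1 at -2.13 (-2.34 to -1.94) and Abcg1 at -1.63 (-1.99 to -1.31). Of the G2/M genes 37 of 39 were lower by size (median -2.24, percentile 0), Cdc25c at -3.27, Ndc80 at -2.98, Ube2c at -2.82 (-3.16 to -2.54) and Ccnb1 at -2.78 (-3.05 to -2.54). Of the S phase genes 29 of 39 were lower by size (median -1.15, percentile 0), with Mcm5 at -2.14 and Ccne2 at -2.08. Of the p53 targets 20 of 24 were higher by size (median 1.03, percentile 100). Gdf15 was at 2.58 (2.44 to 2.73), Btg2 at 1.74, Cdkn1a at 1.72 and Polk at 1.70, and Ckap2 was lower at -1.46. Among 15 CDK inhibitor and cell cycle exit genes, 4 were higher and 5 lower by size (median 0.24, percentile 98.5). Beside Cdkn1a, Ccng1 was at 0.98, whereas Cdkn2c (-1.44) and Rbl1 (-1.24) were lower, and in cyclopamine 2 members were higher and 1 lower (median 0.05, percentile 77.9).

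Genes of cardiac excitation and of the contractile apparatus were lower in part in the GANT61 library. Of 37 calcium handling and ion channel genes, 10 were lower and 2 higher by size (median -0.32, percentile 0.03). Hcn4 (chromosome 9, 58823412 to 58863175), a pacemaker channel gene, had 629 counts in DMSO and 61 in GANT61, a log2 fold change of -3.29 (-3.73 to -2.95). Cacna1h, a T-type calcium channel gene, was at -1.17. In cyclopamine the same list had 1 member higher and 2 lower by size (median -0.08, percentile 1.30). Of the sarcomere genes 2 were higher and 7 lower by size (median -0.17, percentile 0.31), among them Tcap (-1.82) and Tnni1 (-1.72), the slow skeletal troponin I gene of the immature heart, and higher Myom2 (1.77) and Csrp3 (0.89). Of the fetal genes 1, the natriuretic peptide gene Nppb (1.33), was higher and 7 lower by size (median -0.29, percentile 0.19). Of the mature genes 7 were higher and 4 lower by size (median -0.02, percentile 26.7), with Ppara at 1.18 and Mb at 0.95, and with Fhl2 at -1.37 and Ckm at -1.20. Aqp4 was at -3.08 (-3.28 to -2.91), Susd2 at -3.60 (-4.20 to -3.18), Tnr at -3.10 and Wfdc1 at -2.98. Klhdc7a, at 3.23 (3.01 to 3.48), Ano3, at 2.42, and Nmrk2, a nicotinamide riboside kinase gene, at 2.16, were among the 10 named genes with the highest fold. Of the 42 lists measured, 12 had a median above the middle 95% of random lists and 12 below it in each comparison against DMSO. With the spread between the inhibitors simulated, 3 of 42 lay outside it for cyclopamine and 2 for GANT61. That simulation drew each gene independently, and 1 library per group cannot show how far whole lists vary between cultures.

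Stress genes and markers of other cells also differed in GANT61. Of 28 measured targets of NRF2, the transcription factor of the oxidative stress response, 7 were higher and 0 lower by size (median 0.32, percentile 100), with Gsta1 at 3.01 on 15 counts in DMSO, Osgin1 at 1.73, Hmox1 at 1.60 and Slc7a11 at 1.17. Gsta1 shares 89.7% of its 50-base windows with another annotated gene, so its level is uncertain. In cyclopamine 0 of these were higher and 1 lower (median 0.05, percentile 72.6). Of 27 genes of the integrated stress response 11 were higher and 3 lower by size (median 0.31, percentile 100), with Atf3 at 1.73 and Ddit3 at 1.51, against 4 and 1 in cyclopamine (median 0.18, percentile 100). Of 26 immediate early genes 10 were higher and 3 lower in GANT61 (median 0.37, percentile 100), with Nr4a3 at 2.02 and Myc at 1.31, and 7 and 1 in cyclopamine (median 0.22, percentile 100). Of 19 inflammatory and NF-kB genes 9 were higher and 0 lower in GANT61 (median 0.67, percentile 100), led by C3 and Saa3 on 4 and 1 counts in DMSO, and 1, Ccl2 (1.35), was higher in cyclopamine (median 0.14, but -0.065 with the stricter filter). Metallothionein genes Mt2 (2.07) and Mt1 (1384 counts) stood higher in GANT61 too (list median 0.58, percentile 99.6, against 0.77 and percentile 100 in cyclopamine). Collagen and matrix genes had a median of -0.40 (percentile 0), with 3 higher and 12 lower by size, among them Col15a1 (-1.99) and Col14a1 (-1.64). Fibroblast markers had a median of -0.32 (percentile 0.68), endothelial markers -0.28 (percentile 5.85) and smooth muscle and pericyte markers -0.44 (percentile 0.67). By size 1 member of each of these lists was higher, and 7, 5 and 4 were lower. Thy1, which encodes CD90, the antigen used to deplete fibroblasts, had 3050, 2834 and 1207 counts. Markers of the epicardium and mesothelium went the other way: of 16 measured, 10 were higher and 0 lower by size (median 0.68, percentile 100), Upk1b (chromosome 16, 38773184 to 38800328) at 2.90 (2.53 to 3.39), Lrrn4 at 2.80 (2.49 to 3.21), Upk3b at 2.74 (2.34 to 3.28) and Bnc1 at 2.54 (2.08 to 3.18). These genes rested on few counts, 53 for Upk1b and 45 for Upk3b in DMSO. With the stricter filter, which drops members that reach 5 CPM only in GANT61, the median was 0.26. In cyclopamine 3 were higher and 3 lower (median -0.04, percentile 44.3). In all, 1308 genes were higher and 2070 lower by size in GANT61, against 131 in total from simulated counting noise and 2283 from the spread between the inhibitor libraries. With the stricter filter the total of 3378 was 1460.

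GANT61 was then compared with cyclopamine directly, at doses that cannot be matched. The GANT61 library was lower in G2/M genes (median -0.67, percentile 0, 22 of 39 lower by size). S phase genes differed less (median -0.25, percentile 0.12, 5 of 39 lower and 1 higher by size). The p53 targets were higher (median 0.67, percentile 100, 13 of 24 higher by size). Nusap1 was at -1.46, Ttk at -1.31, Gdf15 at 1.42 (1.32 to 1.52) and Cdkn1a at 0.81 (0.78 to 0.83). Cholesterol genes were slightly lower in GANT61 (median -0.21, percentile 0.02), 2 of 25 by size, Tm7sf2 (-0.86) and Nsdhl (-0.67). Mesothelial markers were higher (median 1.33, percentile 100, 12 of 16 by size, but a median of 0.509 with the stricter filter), and Wnt7a was at 2.14 (1.88 to 2.45) and Lrrn4 at 2.12 (1.86 to 2.43). NRF2 targets were higher (median 0.26, percentile 100, 7 of 28 by size), with Osgin1 at 1.66 (1.48 to 1.86). Calcium handling and ion channel genes were lower (median -0.28, percentile 0, 8 of 37 by size), with Hcn4 at -2.08 (-2.54 to -1.71). Selenop, a secreted selenium carrier gene, was at -1.79 (-1.85 to -1.73) with 9875 counts in cyclopamine and 2657 in GANT61. Of 11 measured macrophage and leukocyte markers 5 were lower by size in GANT61 and 1 higher (median -1.02, percentile 0.31), Lyz2 with 465 counts against 163, and against DMSO the list's medians were 0.43 in cyclopamine (percentile 97.8) and -0.70 in GANT61 (percentile 7.73). Mitochondrially encoded genes had a median of -0.47 (percentile 0), against -0.03 (percentile 32.9) for cyclopamine and -0.39 (percentile 0.31) for GANT61 relative to DMSO. Of the genes named above, Mt2, Ccnb1, Mb, Fdft1 and Idi1 share from 30.5% to 45.5% of their 50-base windows with another annotated gene, and their levels carry that uncertainty. On the mitochondrial list mt-Atp6, mt-Co2, mt-Co3, mt-Nd3 and mt-Nd4l share from 98% to 100% of their sequence windows with another annotated gene and hold few counts, so their levels are uncertain. The deep genes mt-Nd1, mt-Nd5 and mt-Cytb, which share 0%, 7.61% and 0%, were at -0.36, -0.47 and -0.40 in GANT61 against cyclopamine. Against DMSO they were at -0.03, 0.71 and -0.14 in cyclopamine and at -0.39, 0.24 and -0.54 in GANT61, so the deep genes differed from each other in direction. Ribosomal protein genes had a median of 0.15 (percentile 100), against -0.07 (percentile 0.16) and 0.05 (percentile 67.3) relative to DMSO, and 0 of 43 differed by size between the inhibitors. In all 960 genes were higher and 1375 lower by size. The total was 2335, and 753 with the stricter filter. The simulated spread gave 2288, but that spread was fitted to these same 2 libraries. The near match was therefore built in and carries no result.

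The comparison that the authors' column headings imply sets both inhibitor libraries as a single arm against DMSO. It leaves 1 residual degree of freedom, and its spread contains the difference between the compounds, with the lone DMSO library assumed to vary alike. edgeR's quasi-likelihood test called 0 of 15576 genes at a Benjamini-Hochberg adjusted p under 0.05 (smallest adjusted p = 0.0814), with 977 genes at an unadjusted p under 0.05. limma-voom called 0 genes (1063 unadjusted), and DESeq2's Wald test called 126, 58 higher and 68 lower (719 unadjusted). With GANT61 as the lone library instead, edgeR called 0 genes (2429 unadjusted), limma-voom 0 (2199) and DESeq2 335 (1546). With cyclopamine as the lone library each tool called 0 (69, 76 and 50 unadjusted). edgeR called 482 genes of 22450 without the expression filter. By size, 853 genes were higher and 1481 lower in the mean of both inhibitors. The total of 2334 compares with 120 from simulated counting noise and 1802 from the spread between the inhibitors, and was 732 with the stricter filter. Mt2 had a mean log2 fold change of 2.66, Klhdc7a of 2.59 and Fdft1 of 2.17, and Wscd2 of -2.65, Dlgap5 of -2.54, Susd2 of -2.52 and Cnn1 of -2.29. Adjusted over the list alone, edgeR's test called 38 G2/M genes, 23 cholesterol genes, 22 S phase genes and 16 p53 target genes, against 0 adjusted over all genes for each list. camera with a preset correlation called 15 of 42 lists, 10 higher and 5 lower, among them the G2/M, S phase, cholesterol and p53 lists. With an estimated correlation camera called 0. That version rests on the 1 residual degree of freedom, which left a call hardly within reach, so its 0 calls carry no result. fry called 0.

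Fold changes of the inhibitors against DMSO were related across genes. Pearson's r was 0.583 and Spearman's rho 0.558 over 15576 genes, which are not independent replicates. Both comparisons share the DMSO library. Unchanged libraries drawn against a shared control gave r = 0.502 with counting noise alone and 0.50 with the spread between the inhibitors. The covariance was 0.225, against 0.031 and 0.146 in those simulations. By size, 326 genes were higher and 753 lower in both comparisons, where independent lists would share 53.6 and 150.6. The simulations shared 12.0 and 8.49 genes with counting noise alone, and 404 and 367 with the spread between the inhibitors. Part of the overlap may come from the shared DMSO library, which cannot be split. Against the wider simulation, the shared higher genes were fewer (326 against 404) and the shared lower genes more (753 against 367). The lists differed in size, with 1771 genes past the size rule in cyclopamine and 3378 in GANT61, against 2300 and 2283 simulated. The shared numbers alone therefore do not show whether a smaller or larger part of each list was in common. Opposite directions by size were seen for 18 genes, a number that the shared DMSO library also lowers.

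**Figure D3:**
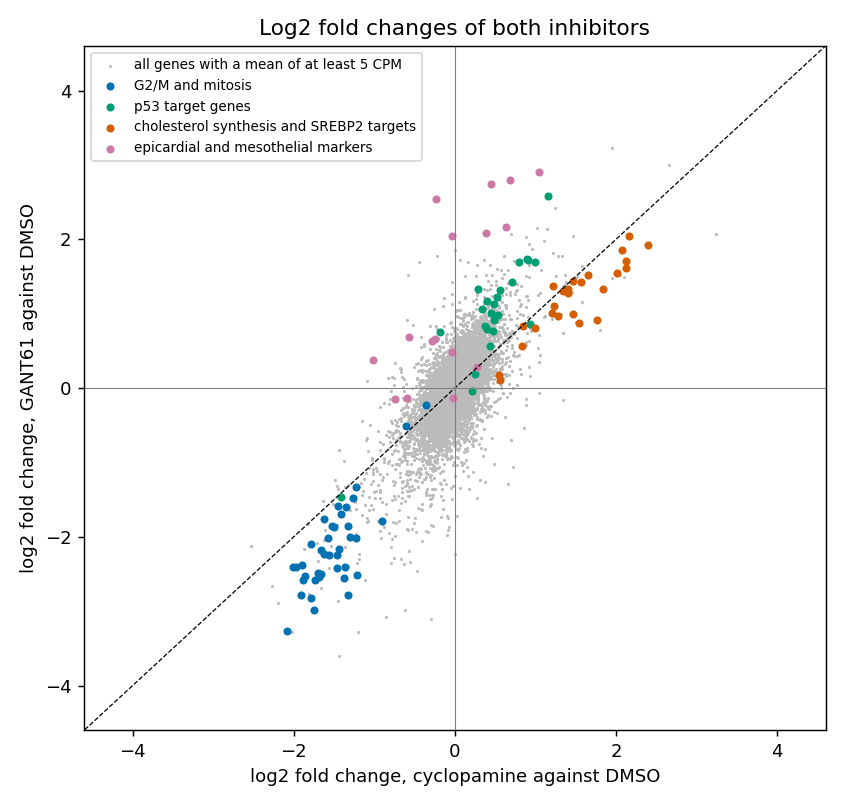
Log2 fold change of cyclopamine (x axis) and GANT61 (y axis) against DMSO, 1 point per gene, with grey for genes with a mean of at least 5 CPM and colours for the members of 4 gene lists; the dashed line marks equal change. G2/M genes lie below the dashed line at the lower left, cholesterol genes lie near it at the upper right, and several mesothelial genes are high in GANT61 with small cyclopamine values.

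The authors' deposited tables list 6612 genes as higher and 6461 as lower in the inhibitors. Each of these 13073 rows equals a row of the raw count table. The lists are as long as the sets of genes whose mean inhibitor count differed by more than 1.2-fold from DMSO without scaling for depth. Whether they hold the same genes was not compared gene by gene. Of the genes that the authors' deposited tables list, 3537 (53.5%) of the higher and 2899 (44.9%) of the lower had fewer than 10 counts in the larger of the compared means. The inhibitors stood on opposite sides of DMSO for 682 and 415 of the genes in the authors' deposited tables. Of the listed genes 3253 higher and 3548 lower passed the expression filter used here, and these include the 853 and 1481 genes that differed by size in the mean of both inhibitors.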

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

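No paired analysis was possible because the count columns carry no replicate number and each group has 1 column. Leaving out a replicate, a fit of only the groups compared and tests of the pairwise comparisons were not run for the same reason. The size rule, its settings and the 5 CPM mean were chosen after seeing the data. The test of both inhibitor libraries against DMSO called 0 genes with edgeR, and also with DESeq2 size factors, limma-voom and the stricter filter. An adjusted p under 0.01 and the 1.2-fold minimum only narrow the same call, so their 0 followed from it. The test called 18 with library size only, 126 with DESeq2, 482 with no filter on low counts and 19 at an adjusted p under 0.1. The cause was not tested. For lists, camera called 15. It called 0 with an estimated correlation, where 1 residual degree of freedom left a call hardly within reach. With the stricter filter camera called 23 of 38 lists, and fry called 0 lists. Genes past the size rule numbered 1771 for cyclopamine, 3378 for GANT61, 2335 between the inhibitors and 2334 for their mean. With at least 5 CPM in 2 libraries, which tests fewer genes, they numbered 447, 1460, 753 and 732. A 1.2-fold minimum gave 3831, 6616, 5213 and 4883, and a 2-fold minimum gave 952, 1820, 1141 and 1210. Other scalings, no filter and no counting interval left each count within 1.5 times. The fold change correlation of 0.583 was 0.697 with the stricter filter, 0.637 over genes past the size rule in either comparison and 0.719 over genes with a mean of at least 5 CPM. No value without an effect was simulated for these gene sets, and the cause was not tested.

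List medians moved little: 478 of 488 recomputed medians lay within the bootstrap interval of the reported value. The mesothelial median was 0.26 in GANT61, 0.509 between the inhibitors and -0.105, a reversed sign, in the mean of both inhibitors with the stricter filter, which drops members that reach 5 CPM only in GANT61. The endothelial median between the inhibitors was -0.233 with that filter. Ribosomal protein medians were -0.101 in cyclopamine and 0.182 between the inhibitors with library size only, and 0.019 in GANT61 and -0.024 in the mean with the stricter filter. The fatty acid oxidation median in cyclopamine was -0.004 with library size only and -0.001 with the stricter filter, and the inflammatory and NF-kB median there was -0.065 with that filter. The cause of these smaller shifts was not tested. Of 3564 recomputed values of named genes and list members, 3511 lay within the counting interval, 53 moved beyond it and 0 of those past the size rule reversed. These settings shifted all genes by little, the median in cyclopamine from -0.004 to -0.030 with library size only. A difference of 1.5-fold could not reverse under such a shift, so the 0 carries no result. Depth limits genes with few counts, such as Gli1, Shh and Gli2.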

Other observations

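Energy and stress genes differed by list. Of 42 nuclear oxidative phosphorylation genes 0 were past the size rule in cyclopamine and 1, Cox8b, in GANT61, but the medians were 0.13 (percentile 99.9) and 0.12 (percentile 94.5). Of 31 fatty acid oxidation genes 3 were higher and 2 lower in cyclopamine (median 0.02, percentile 56.5, but -0.004 with library size scaling only), and 5 and 2 in GANT61 (median 0.04, percentile 59.1), with Acsl1 at 0.64 and 1.08. Of 20 glycolysis genes the lactate transporter gene Slc16a3 stood apart at -1.23 and -1.62 (list medians -0.06, percentile 3.52, and -0.03, percentile 22.5). Of 20 hypoxia genes 0 were past the size rule in cyclopamine (median -0.11, percentile 0.73) and 5 in GANT61 (median 0.00, percentile 38.2). Of 31 lysosome and autophagy genes 4 were higher and 0 lower in each comparison (medians 0.14, percentile 99.9, and 0.20, percentile 99.3). Gpnmb was at 1.58 and 1.15, and Flcn at 0.69 and 1.29. Endoplasmic reticulum chaperone genes leaned lower (medians -0.08 and -0.26, percentile 0.08 in GANT61), with Calr at -0.64 in GANT61. Heat shock genes had medians of 0.13 (percentile 98.1) and 0.14 (percentile 90.0), and 5 measured AhR targets 0.01 (percentile 54.4, but -0.017 with library size scaling only) and 0.27 (percentile 91.3), with 0 past the size rule. Apoptosis regulators had medians of 0.07 (percentile 89.4) and 0.11 (percentile 88.2), with Bid at 0.61 and 1.78 and Bmf at 0.00 and -2.02.

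Cardiac transcription factor genes had a median of -0.01 in cyclopamine (percentile 26.4) and -0.26 in GANT61 (percentile 0.14), where Tbx3 (-1.16), Tbx2 (-1.10), Tbx20 (-0.87), Hopx (-0.68) and Smyd1 (-0.59) were lower by size. TGF-beta and BMP targets had medians of -0.27 (percentile 0) and -0.17 (percentile 2.20), with Ltbp3 at -0.68 and -0.96. Notch targets were at -0.30 (percentile 4.92) and -0.32 (percentile 13.5), with Heyl at -1.02 and -1.67. YAP targets were at 0.14 (percentile 97.8) and 0.29 (percentile 99.5), with F3, the tissue factor gene, at 1.06 and 1.58. Wnt targets went both ways (medians 0.03, percentile 70.4, and 0.13, percentile 88.3), with Dkk3 at 0.89 and 1.24 and Nkd2 at -0.93 and -1.93. Interferon response genes had medians of 0.02 (percentile 71.1, but -0.009 with library size scaling only) and -0.08 (percentile 46.9), and Schwann and neural markers 0.03 (percentile 68.9) and 0.14 (percentile 87.8). Of 10 erythroid markers 0 passed the filter.

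The tests below were chosen after the values had been seen, except the match on GC content and length. Cholesterol synthesis genes were higher in both inhibitor libraries. GC content or transcript length does not account for this, since the list median lay at percentile 100 in both comparisons among 10000 lists matched on expression, GC content and length. A deviation of the DMSO library alone cannot be told apart from a response, because there is 1 DMSO library, and the median of -0.21 between the inhibitor libraries shows only a small difference not due to DMSO. Low cell sterol stays open as a hypothesis: it would lower the LXR-driven sterol exporter genes Abca1 and Abcg1. The highest of their 4 log2 fold changes was -1.63, but these values had been seen first and give it no separate test. These 2 genes do not stand for the 20 LXR targets and fatty acid synthesis genes, whose medians were 0.37 and 0.27. By size 8 of the 20 were higher and 2 lower in cyclopamine, and 7 and 4 in GANT61. Inhibition of Hedgehog signalling as the origin stays open and was not tested.

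Cell cycle genes were lower in both inhibitor libraries, more so in GANT61. A loss of fibroblasts or endothelial cells that lowered their markers as much as the G2/M genes is argued against by 39 markers. Their medians of -0.26 and -0.30 lay above the G2/M medians by at least 1.04 at the lower bound of the bootstrap 95% interval. That interval resamples genes within 1 library per group and does not cover variation between cultures. A loss of only the dividing cells among them would lower the markers less, so the test cannot decide on it. A partial loss stays open beyond the CD90 depletion of fibroblasts. In GANT61 7 of 20 fibroblast and 5 of 19 endothelial markers were lower by size, and 1 of each list was higher. Thy1 was at -1.30. Over all genes 2070 of 15576 were lower by size in GANT61, and the endothelial median lay within the middle 95% of random lists (percentile 5.85). A deviation of the DMSO library alone cannot be told apart from a response for the shared part, since there is 1 DMSO library, but would leave the inhibitors alike, and the G2/M median between them was -0.67. A graded p53 response stays open as a hypothesis: 19 of 24 p53 target genes were ordered DMSO, cyclopamine, GANT61, which restates the list medians already seen and gives no separate test.

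Mesothelial genes were higher in the GANT61 library. A wrong scaling factor would move all genes alike and does not account for it, since the list median between the inhibitors lay at percentile 100 among random lists of like expression. More mesothelial cells and higher expression within other cells cannot be told apart, because levels per cell type are unknown. A like factor for each marker would be the simplest sign of more cells, but Wt1 was at 0.66 (counting interval 0.23 to 1.13) and Upk3b at 2.74 (2.34 to 3.28), and Wt1 RNA from other cells could hide a larger factor. With 1 library per group, a difference between cell preparations may equally give this pattern.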
